A study of Homo sapiens with 4 samples.

How the data were processed

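RNA was sequenced from cells labelled MCF-7 that had been transfected with miR-592 mimics (2 libraries) or mimics NC (2 libraries), per the labels. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, RNA was harvested with Trizol and libraries were made from total RNA with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0 were used by the submitters, and the notes name the mouse build mm9. The gene identifiers and symbols of the deposited table are human, so that build name was not followed. Roles, settings and the annotation release are not given in the sources used here. Groups and replicate numbers were taken from the sample labels.

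The deposited table holds FPKM values, fragments or reads per kilobase of gene scaled to the depth of the library, a unit that was inferred from the values. Multiplied by the annotated length of the gene, 65.5% to 66.8% of the low values of a library fell within 0.02 of whole multiples of a step. The other low values did not. The step of each library was taken as the value of 1 read. From these steps the total of each library was recovered, and each gene's values were turned into reads. With union exon lengths of GENCODE release 29 (GRCh38), 6046 of the 15149 genes above 0 (39.9%) gave whole reads in every library where they were above 0. The tolerance for this was a separate one, narrower for low counts. For the other 9103 genes the length was searched that made all 4 values whole. A length chosen in this way makes its own values whole, so the recovered reads of these genes rest on the assumption of whole counts. The sums of the recovered reads exceeded the recovered totals by 0.338% to 0.355%. Of the identifiers, 19897 matched the annotation and 19871 of these are protein-coding genes, and 14 symbols occurred on more than 1 identifier. The share of reads on mitochondrial-encoded genes was 3.41% to 3.60%. Depth ran from 13328872 to 15978313 reads, and 3 reads in the shallowest library, the floor used here, correspond to 0.0162 FPKM for ESR1 and 0.408 FPKM for TFF1. Intervals and floors cover counting error only.

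The main test was planned on counts. Because the table holds FPKM, which are not counts, limma (version 3.58.1, R 4.3.3; empirical Bayes with a mean-variance trend) was applied to log2(FPKM + 1) for the 9822 genes with a mean of at least 1 FPKM, with the group as the sole term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Fold changes are miR-592 mimics minus mimics NC on the log2(FPKM + 1) scale, which understates changes of low genes. CYP20A1 was tested by itself with a two-sided exact permutation test of the 4 values. Its read rate was compared between pooled groups with an exact Poisson test and with genes of 50 to 150 mean reads.

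Of 32 gene lists fixed before the data were examined, 29 had at least 5 tested members and were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. Camera with an estimated correlation and fry were run beside it. Lists and the mature sequence of miR-592, UUGUGUCAAUAUGCGAUGAUGU, came from general knowledge. Seed sites were the 8mer TGACACAA and 7mer-m8 TGACACA, which pair with positions 2 to 8, and the 7mer-A1 GACACAA, unpaired at position 8. They were searched in the longest annotated 3′ UTR of at least 30 nt of each gene, and 57 tested genes without one were not searched. Camera compared genes with a site to those without, and 2000 bootstrap draws over genes gave the 95% interval. Each of 16378 7-mers found in at least 20 genes was ranked by its coefficient in a linear model of the fold change with log10 3′ UTR length and GC content as covariates (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9.

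Genes were named by a rule fixed before the data were examined. CYP20A1 was always named. Genes past the threshold with a mean of at least 1 FPKM and both miR-592 mimics libraries on the same side of both mimics NC libraries, with a symbol that is no clone or LOC name, were named up to 12 per direction, or, where none passed, the 5 of smallest p as values. From each list described, up to 4 members past the threshold were named, or up to 2 of smallest p, and from genes with a site the 6 of smallest p among the lower ones. Further heat shock members, CRELD1, CDKN2A, the marker genes of the line and the genes called by limma-voom were chosen after their values were seen.

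Apart from the 7-mer ranking, the tests were tried on simulated reads drawn from the real means and totals with the spread of the replicates. For the gene test, 200 of the 9822 genes were changed. Limma recovered 30% of genes changed 1.2-fold, 94% at 1.5-fold, 100% at 2-fold and 100% at 3-fold, and called 8 unchanged genes. Where fewer genes change, the adjusted threshold is harder to pass and these shares may be lower. A list of 20 genes raised by 0.1 had a camera adjusted p of 1.75e-07. Genes were simulated independently of each other, so this cannot show how camera behaves with correlated genes. The 7-mer ranking was tried on the real fold changes shuffled over genes, where a 7-mer whose genes were lowered by 0.05 ranked at 1 of 16378. The shuffle removes any link of the fold changes to GC content and 3′ UTR length, so this rank may overstate what the ranking can find. Other settings fixed beforehand were a replicate block, a pseudocount of 0.1, no minimum and a minimum of 5 FPKM, each library left out, a test against a 1.2-fold change, a minimum absolute log2 fold change of 1, other list tests, the 3′ UTRs of all transcripts and the coding sequence. Added after seeing the data were limma-voom on recovered reads (the same genes, and genes with at least 10 reads in 2 libraries), scaling by the median of ratios, a correction of each library for GC content and log length by quadratic regression, the fit without the trend, a linear model of the site differences with 3′ UTR length and GC content, the heat shock list without HSPA1A and HSPA1B, and the mitochondrial-encoded list without MT-ATP8.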

Results

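Gene expression was measured by RNA sequencing in 4 libraries from cells labelled MCF-7, an established human breast cancer line in wide use as a model of estrogen receptor-positive, luminal disease. In 2 libraries the cells had received miR-592 mimics, synthetic RNAs that stand in for the mature microRNA, and in the other 2 they had received mimics NC, the control transfection. The comparison between the groups asks which messages change when miR-592 is supplied, and the series title names CYP20A1 as its target. The deposited FPKM table covered 19970 genes, of which 15149 were above 0 in at least 1 library and 4821 were listed at 0 in all 4. Library depth, recovered from the steps between low values, was 13328872 and 13362918 reads for mimics NC replicates 1 and 2, and 15105753 and 15978313 reads for miR-592 mimics replicates 1 and 2. Nothing states that the replicates came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. The recovered reads of replicate libraries differed by more than counting noise, with a mean chi-square per gene of 2.29 between the mimics NC libraries and 3.37 between the miR-592 mimics libraries over 3530 genes with a mean of at least 1000 reads. Between libraries of different groups it was 3.17 to 5.77 over the same genes. The SD over genes of the log2 difference was 0.111 and 0.109 within the groups and 0.112 to 0.117 between them. GC content tracked the groups: across genes, its correlation with the log2 difference was 0.0409 and 0.0209 within the groups and 0.247 to 0.297 between them, with higher values of GC-rich genes in the miR-592 mimics libraries (genes are not independent replicates).

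The luminal and estrogen response lists held genes at high levels and genes under 1 FPKM. Of the luminal identity list, 11 of 20 members had a mean of at least 1 FPKM, as did 20 of 34 members of the estrogen response list and 18 of 28 mesenchymal and basal markers. The members given here were chosen after their values were seen. The estrogen receptor gene ESR1 stood at 0.143 ± 0.0361 FPKM (mean ± SD, n = 4 libraries, 19 to 38 reads), and the luminal transcription factor gene GATA3 stood at 0.0819 ± 0.0571 FPKM. The epithelial adhesion gene CDH1 reached 0.0975 ± 0.0460 FPKM, and the estrogen-induced gene TFF1 was listed at 0 in all 4 libraries. TFF3 and AGR2, of the same lists, were also listed at 0 in all 4 libraries. PGR and KRT19 had at most 1 read in a library. GREB1, at 0.258 FPKM, and FOXA1, at 0.858 FPKM, stayed under 1 FPKM as well. The simple epithelial keratin genes KRT8 and KRT18 were abundant, at 358 ± 2.88 and 199.8 ± 4.96 FPKM. Other luminal genes were also expressed, with KRT7 at 71.9 ± 2.68, CLDN4 at 12.6 ± 0.839 and TFAP2C at 10.3 ± 0.818 FPKM. Among mesenchymal and basal markers, KRT5, KRT6A and KRT6B were listed at 0 in all 4 libraries and FN1 stood at 0.890 ± 0.0308 FPKM. VIM, which encodes vimentin, stood at 73.1 ± 3.68 FPKM, CD44 at 71.9 ± 2.57 FPKM and EGFR at 78.7 ± 1.87 FPKM. CDKN2A, a gene that MCF-7 cells are known to lack, stood at 34.7 ± 1.24 FPKM, with 1973 to 2379 reads per library. The levels of ESR1, GATA3, CDH1, TFF1 and CDKN2A go against the MCF-7 label in both groups, so the cells are called the libraries labelled MCF-7 throughout.

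**Figure D1:**
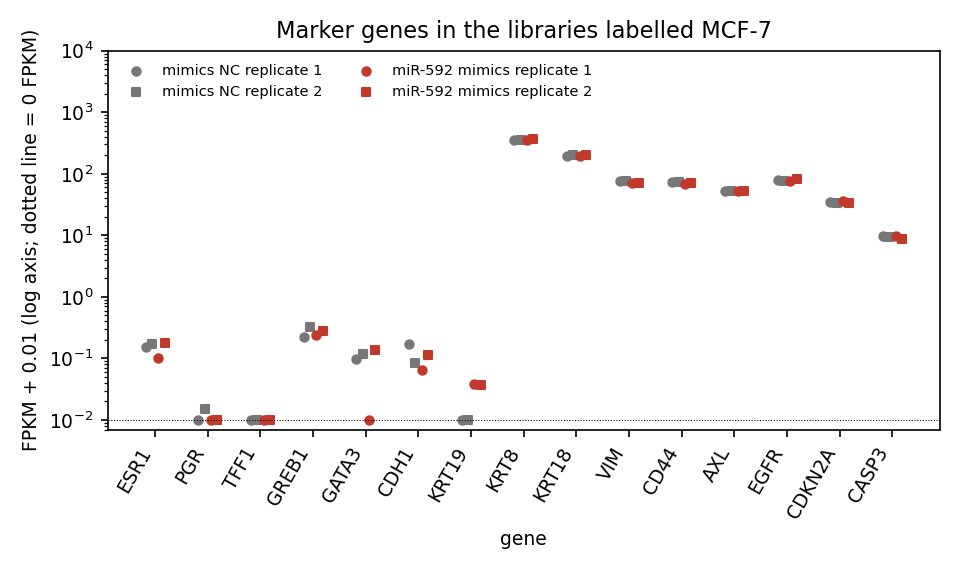
Each point is the FPKM + 0.01 (log axis) of a marker gene in 1 of the 4 libraries, with mimics NC in grey and miR-592 mimics in red, and the dotted line marks 0 FPKM. ESR1, at a mean of 0.143 FPKM, lies under 1 FPKM in each library, while KRT8, at 358 FPKM, VIM, at 73.1 FPKM, and CDKN2A, at 34.7 FPKM, lie above it.

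CYP20A1, a member of the cytochrome P450 family, had lower values in both miR-592 mimics libraries than in both mimics NC libraries. This gene (ENSG00000119004) lies on chromosome 2 at 203238940 to 203305611 of GRCh38. Its FPKM was 0.455 ± 0.0438 (mean ± SD, n = 2) with miR-592 mimics and 0.646 ± 0.0261 (n = 2) with mimics NC, a ratio of means of 0.705. The values came from 78 and 72 reads in the miR-592 mimics libraries and from 94 and 89 reads in the mimics NC libraries. The difference on the log2(FPKM + 1) scale was −0.18, and its two-sided exact permutation p was 0.333, the smallest that 2 libraries against 2 can give. Pooled over each group, the ratio of reads per library read was 0.704, with a 95% interval of 0.563 to 0.878 that covers counting error only and compares these libraries, not the transfections. Of 1473 genes with 50 to 150 mean reads, 6 (0.407%) had as low a ratio or lower and 25 (1.70%) moved as far in either direction. The gene lay below the minimum of 1 FPKM for the test over all genes, and without that minimum limma gave an unadjusted p of 0.0151 and an adjusted p of 0.646. On recovered reads, limma-voom gave a log2 fold change of −0.51 (SE 0.20) with an adjusted p of 0.379. The annotated 3′ UTR of 543 nt held no seed site of miR-592. The deposited values imply a gene length of 10619 nt against 3079 nt in the annotation used here, and the additional sequence was not searched.

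**Figure D2:**
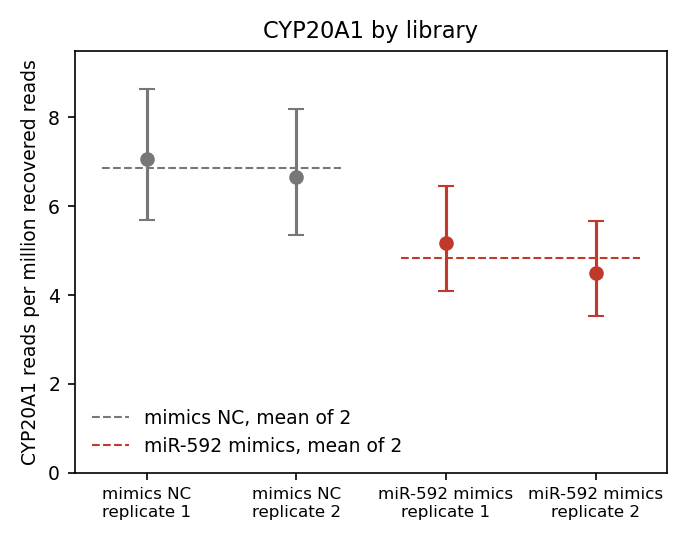
Points are CYP20A1 reads scaled to library depth (per 1e6 recovered reads) in each library, bars are exact 95% Poisson intervals (counting error only) and dashed lines are the means of the 2 libraries of a group. The mimics NC libraries sit at 7.05 and 6.66 and the miR-592 mimics libraries at 5.16 and 4.51.

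Across the 9822 genes with a mean of at least 1 FPKM, 2 genes rose with miR-592 mimics and 0 fell at an adjusted p under 0.05 by limma. HSPA1B (ENSG00000204388, chromosome 6, 31827735 to 31830255) and HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) both encode the stress-inducible chaperone HSP70. HSPA1B rose from 39.2 ± 0.829 to 55.5 ± 0.254 FPKM (n = 2 each), a log2 fold change of 0.49 (SE 0.04) with a limma adjusted p of 0.00234. HSPA1A rose from 54.6 ± 1.47 to 71.5 ± 2.21 FPKM, a log2 fold change of 0.38 (SE 0.04) with a limma adjusted p of 0.0154. The genes are near-identical copies, so the split of reads between them is uncertain. At an unadjusted p under 0.05, limma gave 532 higher and 358 lower genes, against 491 expected by chance in both directions together. No gene reached an absolute log2 fold change of 1, and the largest was 0.79. The groups did not overlap in 39.5% of genes, against 33.3% by chance. In the lower direction, the genes of smallest p, none past the threshold, were HNRNPA1P48 (−0.46), ATP5PF (−0.26), RPL22L1 (−0.24), MT-ATP8 (−0.63) and RPS6 (−0.14, all log2 fold changes), with limma adjusted p from 0.149 to 0.356. With 1 library left out limma called HNRNPA1P48 lower, except without miR-592 mimics replicate 1 (adjusted p of the calls 0.00673 to 0.0178). ATP5PF and MT-ATP8 encode subunits of the mitochondrial ATP synthase, and RPS6 encodes a protein of the small ribosomal subunit. The count of higher genes was 0 with no minimum of expression and 0 without the mean-variance trend. The log2 fold changes of HSPA1B and HSPA1A were the same there, and only the limma adjusted p moved, to 0.375 and 0.646 with no minimum and to 0.545 and 0.611 without the trend. On the other hand, limma-voom on recovered reads called 9 higher and 3 lower of the same genes, and 7 higher and 3 lower of the wider set of genes with at least 10 reads in 2 libraries. In simulated libraries of the same depth, with 200 genes changed, limma recovered 30% of genes changed 1.2-fold and 94% of genes changed 1.5-fold. The adjusted threshold is easier to pass when many genes change, and a common spread was used for all genes. With the 2 genes called here, these shares may therefore overstate what the test could find. Small changes of single genes could pass unseen.

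Heat shock and chaperone genes ranked above other genes with miR-592 mimics. Of 19 tested members, 18 had a log2 fold change above 0, with a mean of 0.12 (camera adjusted p = 5.50e-09). This call was lost with an estimated correlation (camera adjusted p = 0.574 with an estimated correlation). The list mean was higher in both miR-592 mimics libraries than in both mimics NC libraries. Over all genes 2 members passed by limma, HSPA1B and HSPA1A, and adjusted over the list alone 6 did. On recovered reads limma-voom called 4 members over all genes, HSPA8 (adjusted p = 0.00424 on the same genes and 0.00128 on the wider set) and DNAJB1 (0.000989 and 0.00128) besides these. The list mean was 0.122 by limma-voom on the same genes and 0.0670 on the wider set, where it was still called (camera adjusted p = 2.53e-11). The wider set adds CRYAB as member 20, at a log2 fold change of −0.99 (SE 0.39) from 11 to 31 reads per library. The further members were DNAJB1 and BAG3, which encode co-chaperones of HSP70, HSPA8, which encodes the constitutive form of HSP70, and AHSA1, which encodes an activator of HSP90. DNAJB1 stood at 73.9 ± 3.34 FPKM with miR-592 mimics and 62.4 ± 1.38 FPKM with mimics NC (log2 fold change 0.24, SE 0.04). BAG3 stood at 26.3 ± 1.70 against 22.5 ± 0.815 FPKM (0.21, SE 0.05). HSP90AB1 was the member below 0, at −0.01. The call of the list at the preset correlation held with each library left out.

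**Figure D3:**
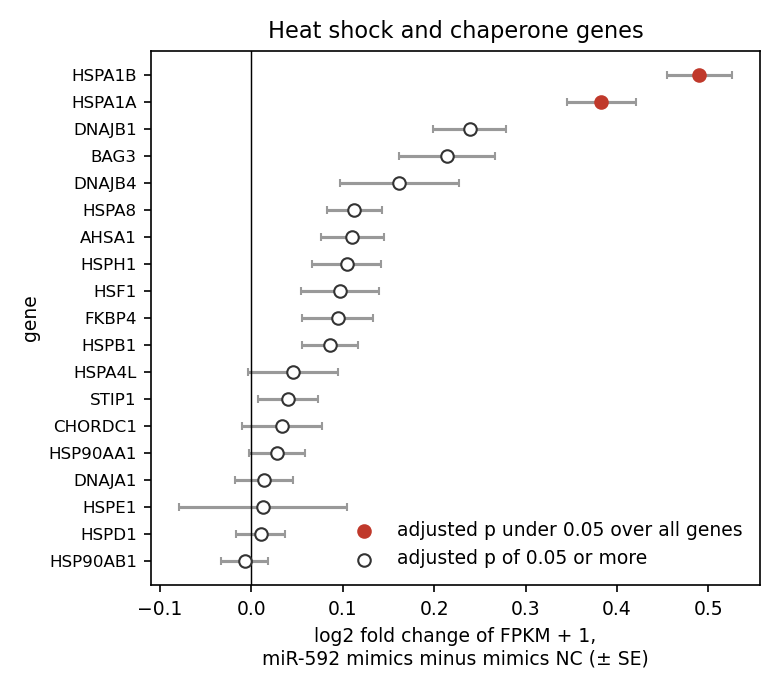
Points are log2 fold changes of FPKM + 1 (miR-592 mimics minus mimics NC, 2 libraries each) for the 19 tested heat shock genes, and bars are limma standard errors. HSPA1B, at 0.49, and HSPA1A, at 0.38, are filled because their adjusted p over all genes was under 0.05, and 18 of the 19 points lie above 0.

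Of the 29 lists with at least 5 tested members, 8 were called by camera at an adjusted p under 0.05, and 0 with an estimated correlation. Of the 8, 3, heat shock included, ranked above other genes. Cholesterol synthesis genes had 20 of 25 members above 0 (mean log2 fold change 0.05, camera adjusted p = 0.0103, but adjusted p = 0.574 with an estimated correlation). Members of smallest p were MSMO1, which encodes a sterol demethylase, at 15.4 ± 0.389 against 12.8 ± 0.358 FPKM and PMVK, which encodes phosphomevalonate kinase, at 34.1 ± 1.28 against 29.6 ± 1.37 FPKM. Over all genes 0 cholesterol members passed by limma, and 2 did adjusted over the list alone. Targets of YAP and TGF-beta had 18 of 21 members above 0 (mean 0.06, camera adjusted p = 0.0111, but adjusted p = 0.574 with an estimated correlation). Their members of smallest p were CCN1, at 122.8 ± 0.842 against 109.3 ± 9.72 FPKM, and F3, which encodes tissue factor, at 6.45 ± 0.130 against 5.46 ± 0.669 FPKM. No YAP and TGF-beta target passed by limma over all genes or adjusted over the list alone (0 members). With 1 library left out, limma called CCN1 over all genes without mimics NC replicate 1 (log2 fold change 0.26 against 0.17 with all 4 libraries, adjusted p = 0.00873) and PMVK without mimics NC replicate 2 (0.25, adjusted p = 0.0346). The cholesterol call was lost without mimics NC replicate 1 (adjusted p = 0.101) and without miR-592 mimics replicate 2 (0.119). Its mean was then 0.0410 and 0.0374, and it was 0.0352 by limma-voom on the wider gene set, where the call held. The YAP and TGF-beta call was lost without mimics NC replicate 2 (0.0503) and without miR-592 mimics replicate 2 (0.0783), with means close to that of all 4 libraries (0.0613 and 0.0623 against 0.0633). After a correction for GC content and length the mean was 0.0456 (adjusted p = 0.0577).

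Genes of the ribosome and of the respiratory chain ranked below other genes with miR-592 mimics. Ribosomal protein genes had 56 of 69 members below 0 (mean log2 fold change −0.04, camera adjusted p = 1.45e-08, but adjusted p = 0.729 with an estimated correlation). Members of smallest p were RPS6 at 317.7 ± 5.31 against 350.1 ± 0.508 FPKM and RPL38 at 48.3 ± 1.03 against 52.2 ± 1.07 FPKM. The groups overlapped for this list: its mean deviation was −0.005 in mimics NC replicate 1 and 0.008 in miR-592 mimics replicate 1, and −0.05 in miR-592 mimics replicate 2 and 0.04 in mimics NC replicate 2. Without mimics NC replicate 2 the mean was −0.0141 (adjusted p = 0.0503), and without miR-592 mimics replicate 2 it was −0.0109 (0.119). It was −0.0625 without mimics NC replicate 1 and −0.0658 without miR-592 mimics replicate 1, against −0.0383 with all 4 libraries, and both were called (camera adjusted p = 2.60e-12 and 8.49e-18). Genes encoded by the mitochondrial genome had 11 of 13 members below 0 (mean −0.08, median −0.04, camera adjusted p = 0.00374, but adjusted p = 0.729 with an estimated correlation). MT-ATP8 carried much of this mean: the other 12 members had a mean of −0.0320, which was called at the preset correlation (camera adjusted p = 0.0167, a setting added after seeing the data). The members of smallest p in the full list were MT-ATP8, at 8.89 ± 1.45 against 14.3 ± 2.84 FPKM, and MT-CO2, at 6632 ± 24.0 against 6963 ± 56.7 FPKM. MT-ATP8 had by far the lowest FPKM of the list. It is also short, at positions 8366 to 8572, so the same FPKM comes from fewer reads than in a longer gene. Limma on log2(FPKM + 1) does not take this into account. MT-ATP6, the other ATP synthase subunit gene of the list, did not share the fall of MT-ATP8. It stood at 2215 ± 15.2 against 2266 ± 134 FPKM, a log2 fold change of −0.03 (limma adjusted p = 0.852). Nuclear-encoded OXPHOS genes had 29 of 41 members below 0 (mean −0.03, camera adjusted p = 0.0103, but adjusted p = 0.729 with an estimated correlation). ATP5PF stood at 13.5 ± 0.290 against 16.3 ± 0.411 FPKM, while UQCRFS1, a member in the opposite direction, stood at 48.3 ± 0.960 against 44.0 ± 0.715 FPKM. Over all genes 0 members of these 3 lists passed by limma on log2(FPKM + 1). Limma-voom called RPS6 lower (adjusted p = 0.0157 on the same genes and 0.0126 on the wider set). It called 0 mitochondrial-encoded members on either set, so MT-ATP8 was not called there. With the replicate number as a block limma called MT-ATP8 lower (adjusted p = 0.00250), as it did with 1 library left out, except without miR-592 mimics replicate 2 (0.109). Adjusted over the list alone, 0 ribosomal, 1 mitochondrial-encoded and 1 nuclear-encoded member passed, all lower. Both mitochondrial calls were lost without miR-592 mimics replicate 2 (adjusted p = 0.116 for the mitochondrial-encoded and 0.751, at a mean of −0.0126, for the nuclear-encoded list) and after a GC and length correction (0.626, at a mean of −0.0344, and 0.0808). The nuclear-encoded call was also lost without mimics NC replicate 2 (0.0503, at a mean of −0.0315), while without miR-592 mimics replicate 1 its mean was −0.0554 (camera adjusted p = 1.19e-05). Also lost was the mitochondrial-encoded call with no minimum of expression (0.0585, at the same mean).

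The other 2 called lists had the smallest means of the 8. Genes of G2/M and mitosis had 25 of 36 members below 0 (mean log2 fold change −0.02, camera adjusted p = 0.0138, but adjusted p = 0.574 with an estimated correlation). Members of smallest p were KIF23, a kinesin gene, at 31.1 ± 0.321 against 33.7 ± 0.383 FPKM and CENPA, which encodes the centromeric histone, at 28.5 ± 0.642 against 25.9 ± 1.42 FPKM, the opposite direction. Genes of the unfolded protein response had 16 of 22 members below 0 (mean −0.02, camera adjusted p = 0.0360, but adjusted p = 0.610 with an estimated correlation). Members of smallest p were HSPA5, which encodes the chaperone of the endoplasmic reticulum BiP, at 475 ± 1.73 against 506 ± 5.28 FPKM and CRELD2 at 8.36 ± 0.649 against 7.20 ± 0.167 FPKM. Over all genes and adjusted over the list alone, 0 members of either list passed by limma. Without each library in turn neither list was called, with adjusted p of 0.0783 to 0.0972 for G2/M and mitosis and 0.0903 to 0.177 for the unfolded protein response, while the means ran from −0.0226 to −0.0205 against −0.0216 and from −0.0225 to −0.0156 against −0.0191. A GC and length correction also ended both calls (0.233 and 0.200, at means of −0.0150 and −0.0155), and the unfolded protein response was not called with no minimum of expression (0.0585, at a mean of −0.0128). It was not called either with a minimum of 5 FPKM (0.0692) or the replicate number as a block (0.0537), both at an unchanged mean, or by limma-voom on the wider gene set (0.0574), where the mean turned to 0.00099. That set adds CRELD1, at a log2 fold change of 0.44 (SE 0.37) from 14 to 28 reads per library.

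The remaining 21 lists were not called. Interferon response genes came nearest (camera adjusted p = 0.153), with 2 of 17 members past the threshold adjusted over the list alone and 0 over all genes. They were IFI6, at 13.3 ± 0.770 against 11.1 ± 0.209 FPKM, and ISG15, at 15.2 ± 1.60 against 12.4 ± 0.756 FPKM. Over all genes limma called ISG15 without mimics NC replicate 1 (adjusted p = 0.0490) and without miR-592 mimics replicate 2 (0.0423). Candidate targets of miR-592 gathered from general knowledge gave a camera adjusted p of 0.447, with 4 of 9 tested members above 0. SPRY2 and CCND3, the members of smallest p, each have a 7mer site. SPRY2 stood at 3.21 ± 0.368 against 2.46 ± 0.285 FPKM and CCND3 at 36.7 ± 0.0581 against 34.0 ± 0.0398 FPKM, both higher in value with miR-592 mimics. Cytochrome P450 genes gave 0.871, with CYP27B1 at 1.70 ± 0.210 against 2.17 ± 0.230 FPKM. The camera adjusted p was 0.371 for E2F targets and DNA replication (ORC6, 11.7 ± 0.167 against 13.1 ± 0.185 FPKM) and 0.598 for p53 targets (TP53I3, 6.23 ± 0.464 against 5.14 ± 0.261 FPKM). It was 0.280 for apoptosis regulators (BAK1, 19.2 ± 0.453 against 16.7 ± 0.736 FPKM) and 0.220 for migration and invasion (ITGA2, 2.97 ± 0.0140 against 2.39 ± 0.273 FPKM). For mesenchymal and basal markers it was 0.639, with SNAI1 at 6.75 ± 0.722 against 5.12 ± 0.0218 FPKM and VIM at 70.0 ± 0.298 against 76.2 ± 1.08 FPKM, and adjusted over the list alone 1 of 18 members passed in the higher and 2 in the lower direction. Luminal identity gave 0.737 and estrogen response 0.598. Replication-dependent histones gave 0.586, with H4C3 at 3.59 ± 0.929 against 5.46 ± 0.926 FPKM and H2BC5 at 6.19 ± 0.590 against 5.03 ± 0.295 FPKM, each past the threshold adjusted over the list alone. The log2 fold change of H4C3 was −0.50 with all 4 libraries. It was −0.65 without mimics NC replicate 2 and −0.71 without miR-592 mimics replicate 1. H4C3 is short (chromosome 6, 26103876 to 26104310), so the same FPKM comes from fewer reads than in a longer gene. Limma-voom on recovered reads did not call it on either gene set.

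For the other lists the camera adjusted p was 0.251 for fatty acid synthesis, 0.251 for metallothioneins and metal transport, 0.251 for immediate early genes and 0.251 for hypoxia and glycolysis. It was 0.371 for PI3K, AKT and FOXO genes, 0.516 for NF-kB and cytokines, 0.516 for ATF4 and amino acid response, 0.598 for microRNA machinery, 0.598 for NRF2 targets and 0.618 for autophagy and lysosome. Mean, median and test differed in sign for 4 lists. The mean log2 fold change was above 0 and the camera direction down for ATF4 and amino acid response (mean 0.01, median −0.01), p53 targets (mean 0.001, median −0.03) and mesenchymal and basal markers (mean 0.02, median 0.01), and the mean and direction were up for candidate miR-592 targets with a median of −0.001. Markers of fibroblasts, leukocytes and endothelium had 4, 0 and 3 members at 1 FPKM or more and were not tested. Their median member stood at 0.0818, 0 and 0.0303 FPKM.

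No lowering was detected of genes whose 3′ UTR could pair with the seed of miR-592. The 271 tested genes with an 8mer site (TGACACAA) differed from the 8175 genes without a site by −0.0075 in mean log2 fold change (95% bootstrap interval over genes −0.0159 to 0.0015, camera adjusted p = 0.899 over the 2 site classes). The 1319 genes with a 7mer site but no 8mer differed by −5.0e-05 (−0.0045 to 0.0042, camera adjusted p = 0.998). With 3′ UTR length and GC content as covariates the differences were −0.00029 (SE 0.0050) for the 8mer and 0.0038 (SE 0.0024) for the 7mer, and with the GC and length correction of each library −0.0018 and 0.0034. Simulated 8mer genes lowered by 0.05 on the log2 scale gave a difference of −0.0334 and a camera p of 8.39e-05. These genes were simulated independently and without a GC trend, while the real fold changes correlated with GC content across genes (0.365). The simulated p may therefore overstate what the real comparison could detect. Of genes with an 8mer or 7mer site, 0 passed the threshold in either direction by limma on log2(FPKM + 1). On recovered reads limma-voom called SRSF3, with an 8mer, lower (log2 fold change −0.14, adjusted p = 0.0319 on the same genes and 0.0329 on the wider set) and ALPI, with a 7mer, higher (0.15, adjusted p = 0.0166 and 0.0151). At an unadjusted p under 0.05 over all genes limma gave 358 lower genes. With 3′ UTR length and the GC content of the 3′ UTR as covariates, genes with the 7mer-m8 site TGACACA differed by 0.0024 (SE 0.0026). This put the site at rank 12222 from the lowest among 16378 7-mers. The site differences above were instead adjusted for the GC content of the transcript. The lower genes with a site and the smallest p were MBIP, at 7.28 ± 0.309 against 9.27 ± 1.11 FPKM, and SRSF3, a splicing factor gene, at 96.8 ± 4.41 against 106.8 ± 0.418 FPKM, both with an 8mer. TFAP2C, TIMM21, HBEGF and RFC3, each with a 7mer, followed at log2 fold changes of −0.18, −0.19, −0.31 and −0.10. The limma adjusted p of these 6 genes was 0.419 to 0.468, and MBIP was called lower without mimics NC replicate 1 (log2 fold change −0.42, limma adjusted p = 0.0114). The direction of the 8mer and 7mer differences turned when some libraries were left out or the coding sequence was searched. In other leave-outs the 8mer difference moved further below 0. It was −0.0152 without mimics NC replicate 2 and −0.0150 without miR-592 mimics replicate 2.

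**Figure D4:**
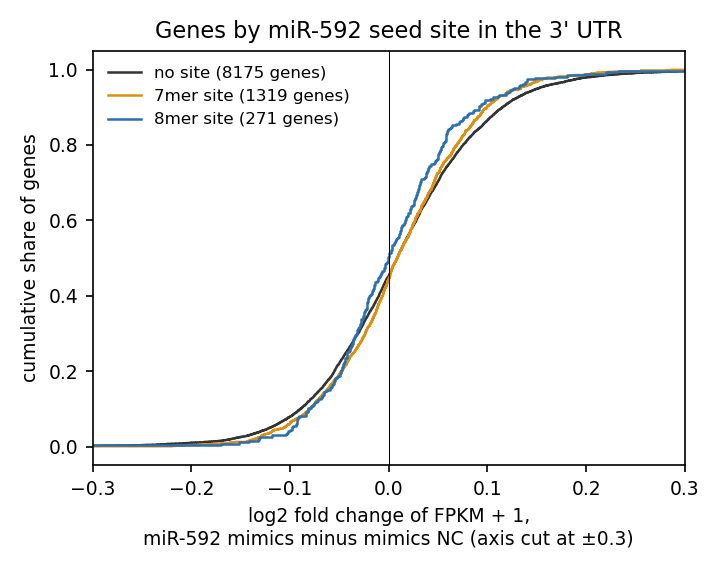
Curves give the cumulative share of genes by log2 fold change of FPKM + 1 (miR-592 mimics minus mimics NC, axis cut at ±0.3) for 8175 genes with no seed site, 1319 with a 7mer and 271 with an 8mer in the longest annotated 3′ UTR. The curves lie close together, with mean differences to genes without a site of −0.0075 for the 8mer and −5.0e-05 for the 7mer.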

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

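The voom, median scaling, GC and length correction, no-trend, without MT-ATP8 and covariate settings were chosen after seeing the data. Of the settings fixed beforehand, those on deposited counts were not run as written: the table holds FPKM, and for 9103 genes the recovered reads rest on a searched length. Limma-voom, median scaling and the read filter stand beside them. Against 2 higher genes, 0 were called with no minimum of expression, 0 without the trend, 0 against a 1.2-fold change and 0 with an absolute log2 fold change of at least 1. On recovered reads limma-voom called 9 higher and 3 lower of the same genes, and 7 higher and 3 lower of genes with at least 10 reads in 2 libraries. With 1 library left out, which leaves a lone library assumed to vary like the other group, higher calls ran from 6 to 40 and lower calls from 5 to 11. The counts were 12 and 5 without mimics NC replicate 1, 40 and 11 without mimics NC replicate 2, 9 and 6 without miR-592 mimics replicate 1, and 6 and 5 without miR-592 mimics replicate 2. The cause was not tested. The replicate number as a block gave 2 higher genes and 1 lower gene (MT-ATP8, limma adjusted p = 0.00250) and 7 lists, the unfolded protein response being lost. Across 9822 genes, the differences of replicate 1 minus replicate 2 were not correlated between the groups (−0.0331). Differences of single genes hold counting noise, so this does not exclude a pairing by number. From replicate 1 to 2, the mean deviation of cytochrome P450 genes rose in both groups (−0.0366 to 0.0324 with mimics NC, −0.0372 to 0.0414 with miR-592 mimics). That of ribosomal protein genes rose with mimics NC and fell with miR-592 mimics.

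Lists called fell from 8 to 3 with the GC correction, 0 with an estimated correlation and 0 by fry, and ran from 1 to 7 with 1 library left out: 5 without mimics NC replicate 1, 4 without mimics NC replicate 2, 7 without miR-592 mimics replicate 1 and 1, heat shock, without miR-592 mimics replicate 2. Among uncalled lists, hypoxia and glycolysis was called without mimics NC replicate 2 (adjusted p = 0.00241) and without miR-592 mimics replicate 1 (0.0278). In 38 of 271 comparisons the mean of an uncalled list changed sign. The count of 0 by fry is that of its directional test. Its mixed test, which allows members to move in either direction, gave adjusted p of 0.0154 for heat shock and the unfolded protein response. The fry mixed adjusted p was 0.0189 for G2/M and mitosis, and for autophagy and lysosome and luminal identity, which camera did not call. The mean of the unfolded protein response turned to 0.00099 by limma-voom on the wider gene set. Over 800 comparisons of named genes, 0 reversed, 20 became called and 6 lost their call, those of HSPA1A and HSPA1B, at unchanged log2 fold changes of 0.38 and 0.49.

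The 8mer difference ran from −0.0152 to 0.00030 with 1 library left out, being 0.00030 without mimics NC replicate 1 and 0.00012 without miR-592 mimics replicate 1, and was 0.0070 in the coding sequence. The 7mer difference ran from −0.0051 to 0.0050, and was 0.00042 with a pseudocount of 0.1, 9.9e-05 with median scaling, 0.0034 with the GC correction, 0.0038 with 3′ UTR length and GC content as covariates, 0.00075 by limma-voom on the same genes and 0.0030 in the coding sequence. None of these passed its test. CYP20A1 kept its direction in each setting that kept the gene, from −0.21 to −0.15 with 1 library left out, −0.43 with a pseudocount of 0.1 and −0.51 by limma-voom. Its adjusted p ran from 0.379 to 0.768, and the minimum of 5 FPKM, the GC correction and the fit without the trend gave it no value. Depth limits this gene, with 72 to 94 reads per library.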

Other observations

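The tests of marker levels and of single libraries for the ribosomal list were chosen after their results were seen, and the GC and length correction, the heat shock list without HSPA1A and HSPA1B, the mitochondrial-encoded list without MT-ATP8 and the fit on recovered reads were added after seeing the data. On recovered reads, limma-voom called 7 genes outside the gene lists among the genes of the main test, and 5 of them also on the wider set of genes with at least 10 reads in 2 libraries, which gave the adjusted p below. PIEZO1, which encodes a mechanically gated channel, stood at 21.7 ± 0.00455 FPKM with miR-592 mimics against 19.1 ± 0.452 FPKM with mimics NC (n = 2 each; limma-voom adjusted p = 0.0295). PLXND1, a semaphorin receptor gene, stood at 25.5 ± 0.603 against 22.4 ± 0.634 FPKM (limma-voom adjusted p = 0.0329), and ALPI, an alkaline phosphatase gene, stood at 223 ± 3.37 against 202 ± 0.632 FPKM (0.0151). TM4SF1, a tetraspanin-like surface protein gene, was lower, at 367 ± 19.6 against 406 ± 4.78 FPKM (limma-voom adjusted p = 0.00799), as was SRSF3, a splicing factor gene with an 8mer site, at 96.8 ± 4.41 against 106.8 ± 0.418 FPKM (limma-voom adjusted p = 0.0329). KIF26A, a kinesin gene, at 27.8 ± 0.163 against 24.4 ± 0.217 FPKM, and PRRC2B, at 31.6 ± 0.236 against 28.5 ± 0.406 FPKM, were called among the genes of the main test alone (limma-voom adjusted p = 0.0450 for each, against 0.0573 and 0.0570 on the wider set). In the test on log2(FPKM + 1) the limma adjusted p of these 7 genes was 0.356 to 0.419.

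The ribosomal and cholesterol calls held in most settings. The heat shock call held in each setting except the estimated correlation and the directional test of fry. A trend of GC content and length between the groups predicts that the mean log2 fold change shrinks once each library is corrected, and it went from 0.119 to 0.113. Reads shared between HSPA1A and HSPA1B would leave the rest of the list without a call, yet without both genes the camera adjusted p was 1.32e-05. A single unusual library would carry the mean, whereas the smallest mean with 1 library left out was 0.107. A response to the mimics is a hypothesis that stays open, as does a difference in handling between the transfections, since each group is 1 set of 2 libraries and the call was lost with an estimated correlation.

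The lower ribosomal and respiratory chain genes may have several sources. For ribosomal proteins the mean log2 fold change was −0.0356 after the GC and length correction and −0.0383 before, which argues against that trend. It was −0.0109 without miR-592 mimics replicate 2 and −0.0141 without mimics NC replicate 2. These 2 libraries deviated in opposite directions (−0.0466 and 0.0434), so most of the mean rests on both of them. The other libraries stood at 0.0082 (miR-592 mimics replicate 1) and −0.0050 (mimics NC replicate 1). For mitochondrial-encoded genes the correction took the mean from −0.0776 to −0.0344, with an SD over members of 0.169 before and 0.16 after. The smaller mean goes with the GC trend as a source of much of it. The call ended too (camera adjusted p = 0.626), but the size of the mean alone does not account for that. Uncorrected and without MT-ATP8, a mean of −0.0320 was called (camera adjusted p = 0.0167). Without MT-ATP8 the correction took the mean from −0.0320 to 0.0082. For nuclear-encoded OXPHOS genes it took the mean from −0.0340 (SD 0.0733) to −0.0264 (SD 0.0729), between the bounds set in advance, and the call ended with the smaller mean, so the trend cannot be told apart from a change of these genes. An effect of the mimics stays open, as untested.

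A part of the luminal and estrogen response genes was low in the libraries labelled MCF-7, with 9 of 20 and 14 of 34 members under 1 FPKM, ESR1 among them, while 11 and 20 had at least 1 FPKM. Too few reads would not explain this, since the highest limit set by 3 reads among the 23 luminal and estrogen response members under 1 FPKM was 0.408 FPKM. CDKN2A, which MCF-7 is known to lack, had at least 1973 reads in each library, consistent with cells of another line than MCF-7. No biological explanation was tested, since the design varies only the mimics.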
